A study of Gallus gallus and Meleagris gallopavo with 16 samples.

How the data were processed

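Total RNA of pituitary glands was measured in 16 samples of female birds, 4 in each of 4 groups. Per the labels, the chicken groups were laying adults and pullets that did not lay, each sample a pool of 5 glands, and the turkey groups were laying adults and photorefractory adults, whose samples were not said to be pooled. Labelled complementary DNA of 1 active and 1 inactive sample of the same species and replicate number was hybridised together to an array of chicken oligonucleotide probes, with a pair of Alexa Fluor dyes. Each such pair was hybridised to a second array with the dyes exchanged, which gave 8 pairs on 16 arrays. The 32 deposited scanner files held each array in duplicate, identical byte for byte, and each array was used 1 time.

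Per the file headers, the scans were read with BlueFuse for Microarrays 3.6 (build 7145), and the deposited spot amplitudes of both channels are intensities in the scanner's arbitrary units. The deposited probability that signal is present in a spot is a fraction per channel, as its column name and its range show. The authors also deposited a table of 1 value per probe and sample, whose unit is a score. Its normalization is not stated, and the slope of a sample's values on its own mean log2 amplitudes was 0.505 to 0.648, so that table served only for a check and as an alternative. The channel that held the active sample was read from the channel codes of the deposited files. On 16 of 16 arrays the direction of the deposited table matched those codes.

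An array held 22176 spots in 48 blocks. These were 20460 probes of the chicken library, 18 custom oligonucleotides, 1480 empty spots and 218 control oligonucleotide spots. The deposited files pair 13097 probes with a gene name. Of these, 11747 were matched to current symbols in a gene table of assembly GRCg7b, used for names only, and 1350 kept the symbol of the file. No symbol was given for 7363 library probes, which were tested and counted but are named only where stated.

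Log2 ratios of active over inactive were computed in limma 3.58.1 (R 4.3.3). Background was modelled with normexp at an offset of 50, although BlueFuse amplitudes are already separated from background by its own model, because this setting had been fixed before the data were examined. Ratios were normalized by loess within each array with empty and control spots at weight 0, and not scaled between arrays. The files give no local background, so a channel counted as above background where its amplitude exceeded the 95th percentile of the empty and control oligonucleotide spots of that array. A probe was kept for a species where it was above background in at least 1 channel on at least 4 of 8 arrays. Both arrays of a dye swap were averaged after the sign of 1 was turned, so that the replicate is the hybridised pair, with n = 4 per species. Means of the 4 ratios were tested against 0 with lmFit and eBayes in each species, and the difference turkey minus chicken was tested in 1 fit of all 8 pairs. Adjusted p-values are Benjamini-Hochberg values over all probes tested in a comparison, with a threshold of 0.05. Errors are SDs over pairs unless called SE, which is limma's moderated standard error. The number of arrays limits the precision of every ratio.

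The share of probes above background and the correlation between both arrays of a swap were compared between species by exact two-sided permutation tests of the pairs. With 4 pairs against 4, these cannot give a p below 0.029. A total of 20 gene lists, 7 of them markers of other cells or tissue that a dissected pituitary can hold, were tested with camera in limma at a preset inter-gene correlation of 0.01, with 1 probe per gene and at least 5 measured genes. They covered pituitary hormones, receptors for hypothalamic factors, steroid, thyroid and prolactin receptors with deiodinases, the activin, inhibin and follistatin system, pituitary transcription factors, and granule and prohormone processing. Further lists were endoplasmic reticulum folding and translocation, cell cycle, ribosomal proteins, oxidative phosphorylation, sterol synthesis, immediate early genes and the circadian clock. The marker lists were collagen and matrix, endothelium, red blood cells, immune cells, neural lobe with neurons and glia, folliculostellate and stem cells, and liver and oviduct transcripts. Camera with an estimated correlation and fry, which asks whether a list moves on balance 1 way without comparing it with other genes, were alternatives. P-values of lists were adjusted over the lists of a comparison.

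The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named, per species, the 10 largest rises and the 10 largest falls past the threshold that went the same way in all 4 pairs and carried 1 symbol, with 1 probe per gene. With under 5 calls it named the 10 probes with a symbol and the lowest unadjusted p. It also named all measured pituitary hormones, list members past the threshold, the largest differences between species, and the probes changed in both. Up to 4 members per list that passed after adjustment over the list alone are also named, as are some custom oligonucleotides and unnamed probes. Those were chosen after their values were seen. Some genes that meet the rule are not reported here, although they are counted.

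The code was tested on simulated data made with the measured spread and dye effect of each of 19695 probes, of which 200 were changed in each of 10 simulations. The same dye effect entered both arrays of a swap and cancelled in their mean, so it had no influence on the rates below. Ratios were simulated as already normalized, so background correction, normalization and the filter were not tested. In chicken, 16% of the 1.5-fold, 61.3% of the 2-fold and 91.8% of the 4-fold changes were recovered, and 4.5% of the calls were false. In turkey, 8.21%, 51.9% and 83.6% were recovered at these sizes, and 3.92% of the calls were false. For the difference between species, 10.1%, 47.5% and 87.1% were recovered, and 10.9% of the calls were false, above the nominal rate. A random list of 23 among 11345 genes, shifted by 0.5 on the log2 scale, was called in 10 of 10 simulations in each species, and 0 of 190 unshifted lists were. Genes were simulated as independent, so this does not test false calls of lists whose genes are correlated. In the data the estimated inter-gene correlation was 0.648 for ribosomal proteins in chicken.

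Alternatives covered background correction, normalization within and between arrays, the filter on dim probes, the model and its variance prior, array weights, the pairing, the deposited table, the scan day as a block, and leaving out each pair. The scan days in the file headers fall into 6 days, and each array holds both reproductive states. Fits with scan day used single arrays and no pair term, so both arrays of a swap entered as separate replicates. A random block of replicate number across species was added later, although deviations of pairs with the same number correlated only at -0.008 to 0.041 between species.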

Results

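The series measured gene expression in the pituitary gland of female chickens and turkeys in reproductively active and inactive states, with an array designed for chicken. There were 4 groups of 4 samples, namely laying adult chickens, pullets not yet laying, laying adult turkeys and photorefractory adult turkeys, which are birds that have stopped responding to long days. Each array compared 1 active with 1 inactive sample of a species, and each of the 8 pairs was measured on 2 arrays with the dyes exchanged. The median probe amplitude per array was 661.5 to 1890.4 in the first channel and 829.1 to 2672.1 in the second. In the median array, empty spots read 428.2 in the first channel and 40.4 in the second.

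The first comparison asked which transcripts differ between the pituitaries of laying hens and of pullets. In laying hens the largest rises among named genes were those of PGDS, a prostaglandin D synthase, at 3.79 ± 0.99 (SD, n = 4 pairs; 13.9-fold; adjusted p = 0.0179), and of LONP1, a mitochondrial protease, at 3.03 ± 0.80 (8.15-fold; adjusted p = 0.0183). Unnamed probes with library numbers close to that of the PGDS probe gave similar ratios, as described under other observations. The melanocortin receptor MC5R rose by 2.38 ± 0.48 (5.22-fold), the relaxin family peptide RLN3 by 2.18 ± 0.56 (4.52-fold), and the progesterone receptor PGR by 1.58 ± 0.32. NR5A1, a transcription factor of the cells that make gonadotrophins, rose by 1.05 ± 0.28 (2.07-fold; adjusted p = 0.0422). The largest falls included those of BPIL3 at -1.81 ± 0.46, LUZP2 at -1.63 ± 0.23, the neuropeptide galanin (GAL) at -1.30 ± 0.39, and CD74, the invariant chain of major histocompatibility class II, at -1.24 ± 0.32.

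Further rises were those of LOC769948 (2.58 ± 0.56), the coagulation inhibitor TFPI (2.43 ± 0.68), C11orf96 (2.21 ± 0.45), LOC769105 (2.19 ± 0.44), the lysophosphatidic acid receptor LPAR3 (2.10 ± 0.58) and the amino acid transporter SLC7A5 (2.03 ± 0.59). Their adjusted p-values were 0.011 to 0.0241. Further falls were those of transferrin (TF, -1.17 ± 0.28), cyclin D1 (CCND1, -1.13 ± 0.30), KIFC2 (-1.07 ± 0.18), NR6A1 (-1.05 ± 0.30), the chloride transporter CLCN3 (-1.02 ± 0.28) and type II collagen (COL2A1, -1.02 ± 0.15). Their adjusted p-values were 0.0218 to 0.0459. A second probe of LOC769948 also passed, at 2.10, whereas second probes of LUZP2, at -1.48 (adjusted p = 0.264), and of COL2A1, at -0.19 (adjusted p = 0.591), did not. LOC769948, TFPI and PGR were above background in 8 of 8 arrays in the channel of hens and in 3 of 8 in that of pullets. BPIL3 was above background in 1 and 5 of 8 arrays, LUZP2 in 2 and 8, KIFC2 in 2 and 4, and NR6A1 in 3 and 6, so their ratios are those of dim spots.

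In all, 79 of 19992 probes tested passed in chicken, 64 higher and 15 lower in hens, and 79 of 79 went the same way in 4 of 4 pairs. That agreement comes from the same ratios that made the calls, so it is no separate support. The 79 probes represented 62 named genes, and 16 of the probes carried no symbol. At an unadjusted p under 0.05 there were 2381 probes, where chance alone gives a share of about 0.05 of the probes tested. The count was 0 with a variance prior that follows intensity and resists outlying probes, and 11 when active and inactive samples were compared unpaired. It was 295 with scan day as a block, in a fit of single arrays without a pair term. Both arrays of a swap entered that fit as separate replicates, so its higher count cannot be credited to scan day. Without pairs 1, 2, 3 and 4 the count was 11, 44, 2 and 0, respectively. Hens and pullets differed in age as well as in laying, and these cannot be separated here.

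Among 6 pituitary hormone genes measured in chicken, follicle stimulating hormone (FSHB) and prolactin (PRL) were higher in hens when adjusted over the list alone. FSHB stood at 1.82 ± 1.07 (4 of 4 pairs; adjusted p = 0.153 over all probes) and PRL at 0.79 ± 0.27 (4 of 4 pairs; adjusted p = 0.0925 over all probes). Growth hormone (GH) stood at -0.22 ± 0.49, proopiomelanocortin (POMC) at -0.02 ± 0.26, the thyrotropin subunit TSHB at 0.27 ± 0.54 and the common subunit CGA at 0.01 ± 0.24. No probe for luteinizing hormone's beta subunit was found by symbol, a search that does not cover the custom oligonucleotides, which carry no symbol.

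The sterol synthesis list was higher in hens, with a median of 0.50 over 23 genes, 21 of them above 0 (adjusted p = 3.27e-11). HMGCS1, the synthase that makes hydroxymethylglutaryl coenzyme A, rose by 1.09 ± 0.28 (adjusted p = 0.0367 over all probes). Adjusted over the list alone, 11 of the 23 rose, among them the methylsterol oxidase MSMO1 (1.23 ± 0.46). Genes of endoplasmic reticulum folding and translocation were shifted up by a median of 0.11 (34 of 41 above 0; adjusted p = 0.00131), with RPN1 at 0.63 ± 0.23 the 1 member to pass when adjusted over the list alone. Oxidative phosphorylation genes were shifted up by 0.10 (49 of 52 above 0; adjusted p = 0.000548), and none of these 52 passed singly (0 over all probes, 0 when adjusted over the list alone, 4 at an unadjusted p under 0.05). With an estimated correlation the adjusted p-values of these 3 lists were 0.0875, 0.627 and 0.786, and none of the 3 calls held. The estimates themselves were -0.001, 0.191 and 0.384, so correlation among the sterol genes does not account for the loss of that call. By fry the sterol list passed in chicken (adjusted p = 0.0113).

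Lists lower in hens were cell cycle, with a median of -0.10 over 64 genes (adjusted p = 0.00411), collagen and matrix, at -0.14 over 30 (adjusted p = 0.00295), and immune cells, at -0.07 over 35 (adjusted p = 0.00411). With an estimated correlation these adjusted p-values were 0.627, 0.453 and 0.601, so the calls were lost. Cyclin D1 was the 1 member of the cell cycle list that passed. Adjusted over the list alone, 4 matrix genes fell, namely SPARC (-0.68 ± 0.40), VIM (-0.66 ± 0.24), MGP (-0.53 ± 0.29) and FBLN5 (-0.46 ± 0.24). On the same terms 5 immune genes fell, among them CD74, LCP1 (-0.90 ± 0.46), CD3D (-0.85 ± 0.52) and CD44 (-0.61 ± 0.38). The collagen and immune lists are markers of cells other than hormone-producing ones, and they moved opposite to the sterol and endoplasmic reticulum lists. The other marker lists and the granule list did not pass in chicken, and the share of each cell type was not measured.

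Steroid, thyroid and prolactin receptor genes went both ways in chicken. Their median was -0.08 and their mean 0.08, and the list did not pass (adjusted p = 0.878). Adjusted over the list alone, PGR and the estrogen-induced gene GREB1 (1.56 ± 0.62) rose, and the estrogen receptors ESR1 (-0.59 ± 0.32) and ESR2 (-0.46 ± 0.10) fell. The other lists did not pass in chicken either. Their medians were 0.14 for pituitary hormones, -0.09 for hypothalamic factor receptors, -0.05 for the activin system, -0.03 for pituitary transcription factors (mean 0.04), 0.09 for granule genes, -0.02 for ribosomal proteins, -0.04 for immediate early genes and 0.09 for the clock. For the remaining marker lists they were -0.01 for endothelium, -0.01 for red blood cells, 0.04 for neural lobe (mean -0.01), -0.10 for folliculostellate cells and -0.01 for liver and oviduct transcripts (mean 0.05).

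The second comparison asked the same of laying against photorefractory turkeys. None of the genes named here passed in turkey. Among those with the lowest unadjusted p, 9 were higher in laying turkeys in 4 of 4 pairs, with adjusted p-values of 0.105 to 0.136. They included the progesterone receptor PGR (1.39 ± 0.28, SD, n = 4 pairs), the glypican GPC4 (1.45 ± 0.21), the fatty acid binding protein FABP6 (2.41 ± 0.55), TESC (1.60 ± 0.30), C11orf96 (1.40 ± 0.27), C9orf61 (1.38 ± 0.32) and ATP13A3 (1.28 ± 0.22). PGR was above background on 6 of 8 turkey arrays in the active and 3 of 8 in the inactive channel, so its ratio is that of dim spots. The disulfide isomerase PDIA3 stood at 1.11 ± 0.18 and S100B at 0.89 ± 0.07.

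FSHB stood at 1.08 ± 0.68 in turkey, higher in 4 of 4 pairs, and GH at -0.44 ± 0.29, lower in 4 of 4 pairs. Adjusted over the list alone FSHB rose and GH fell, but over all probes their adjusted p-values were 0.607 and 0.69. PRL stood at 0.16 ± 0.32, POMC at -0.09 ± 0.10, TSHB at -0.13 ± 0.30 and CGA at 0.21 ± 0.41. In all, 1288 of 19830 probes had an unadjusted p under 0.05, where chance alone gives a share of about 0.05 of the probes tested. Past the adjusted threshold there were 2 probes by limma. The count was 0 with the variance prior that follows intensity, and 22 with scan day as a block and no pair term. It was 0, 2, 0 and 0 without pairs 1, 2, 3 and 4.

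In turkey, too, the sterol synthesis list was higher in active birds, with a median of 0.18 over 23 genes (18 above 0; adjusted p = 3.09e-05). Adjusted over the list alone 7 of the 23 rose, among them SREBF2 (0.76 ± 0.47) and HMGCS1 (0.70 ± 0.39), and 0 passed over all probes (9 at an unadjusted p under 0.05). The endoplasmic reticulum list was shifted up by 0.06 over 41 genes (adjusted p = 0.00358), and adjusted over the list alone 6 of them rose, among them PDIA3, HYOU1 (0.54 ± 0.28), CANX (0.51 ± 0.14) and CRELD2 (0.51 ± 0.22). Ribosomal protein genes were shifted up by 0.09 over 56 (adjusted p = 0.000658), and collagen and matrix genes down by 0.12 over 30 (median -0.12; adjusted p = 0.00637). With an estimated correlation the adjusted p-values of these 4 lists were 0.261, 0.693, 0.81 and 0.508, so none of the 4 calls held. The estimates themselves were -0.02, 0.068, 0.331 and 0.012. By fry the sterol list did not pass in turkey (adjusted p = 0.115).

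The other lists did not pass in turkey. Granule and prohormone processing genes had a median of -0.05, and adjusted over the list alone SCG3 rose (0.42 ± 0.15) while SYT1 (-0.84 ± 0.57) and PCSK2 (-0.45 ± 0.07) fell. Medians were 0.03 for pituitary hormones, 0.02 for hypothalamic factor receptors, 0.01 for steroid and related receptors, -0.02 for the activin system, 0.02 for pituitary transcription factors, -0.01 for cell cycle, 0.04 for oxidative phosphorylation, -0.01 for immediate early genes and 0.03 for the clock. Among marker lists they were 0.06 for endothelium, -0.12 for red blood cells, -0.06 for immune cells, -0.01 for neural lobe (mean 0.03), -0.06 for folliculostellate cells and -0.03 for liver and oviduct transcripts.

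**Figure D1:**
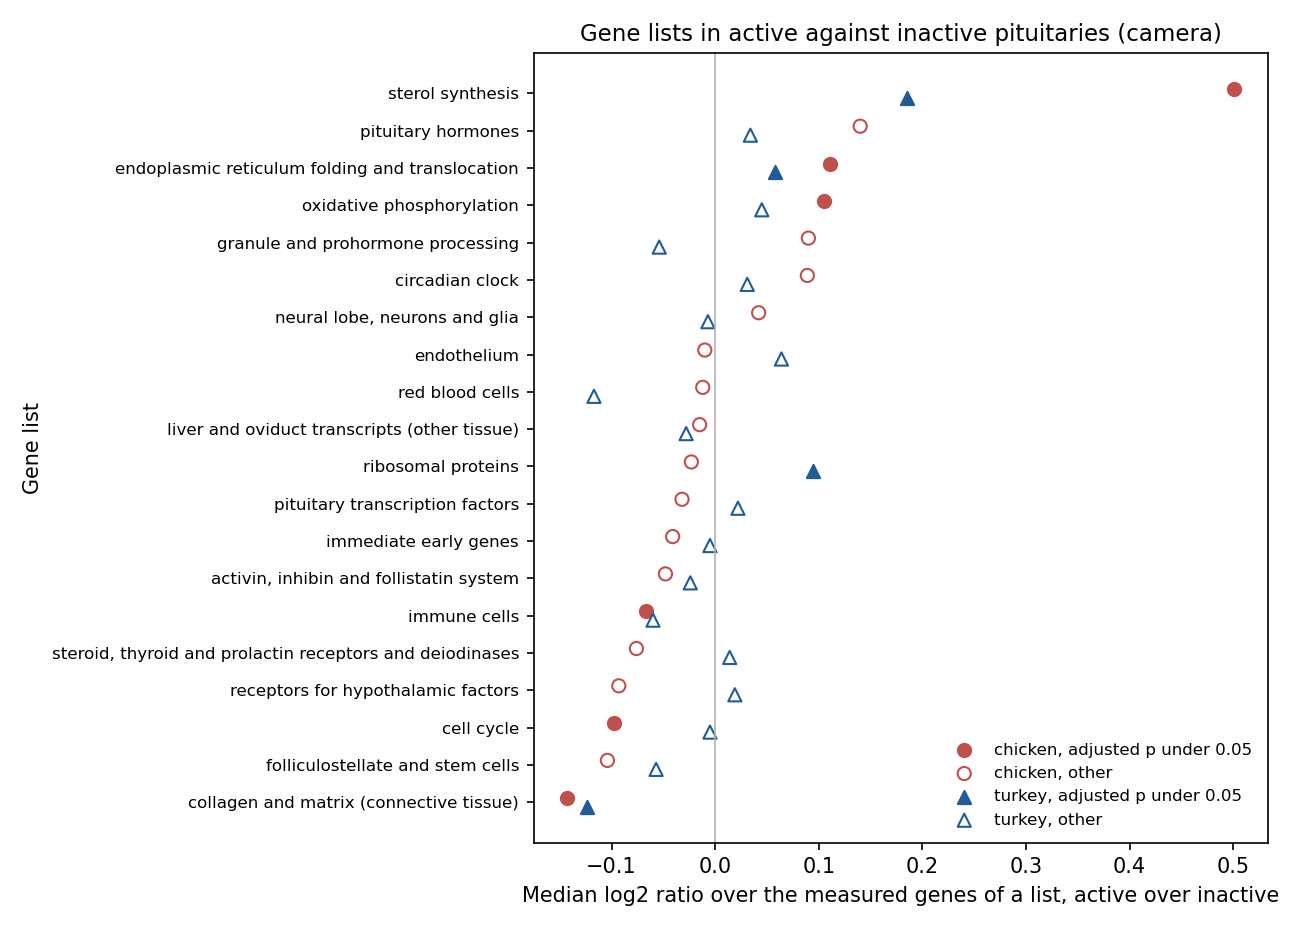
Median log2 ratio of active over inactive (x axis) for each gene list (y axis) in chicken (circles) and turkey (triangles), 4 pairs per species; filled symbols have a camera adjusted p under 0.05 at the preset correlation. The sterol synthesis list has the highest median in both species, 0.50 in chicken and 0.18 in turkey.

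The third question was how far the ratios measured with turkey RNA followed those in chicken. RLN3 stood at 2.18 ± 0.56 in chicken and 2.14 ± 0.92 in turkey, GPC4 at 1.54 ± 0.18 and 1.45 ± 0.21, PGR at 1.58 ± 0.32 and 1.39 ± 0.28, and C9orf61 at 1.37 ± 0.16 and 1.38 ± 0.32. Of 78 probes called in chicken and tested in turkey, 61 went the same way in turkey. These were 57 of the 64 that were higher in hens and 4 of the 14 that were lower. The threshold was passed in both species by 1 probe, where 0.0065 would be expected by chance. Adjusted over the list alone, the list being the one called in chicken, 23 passed in turkey the same way and 1, CRABP1, the opposite way. The median change over the 78 probes was 1.29 in chicken and 0.33 in turkey in the direction called in chicken, where the former is raised by selection on it.

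Over all 19695 probes kept in both species the mean ratios correlated at Pearson r = 0.149 and Spearman rho = 0.11, across probes, which are not independent replicates. Single chicken and turkey pairs correlated at -0.0342 to 0.143 (median 0.0608), chicken pairs with each other at 0.132 to 0.28 (median 0.215), and turkey pairs with each other at 0.00144 to 0.136 (median 0.0723). Both pairs scanned in full on the first scan day, 1 of each species, correlated at 0.089. Where only probes above background in both channels of every array were kept, r between species was 0.306.

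**Figure D2:**
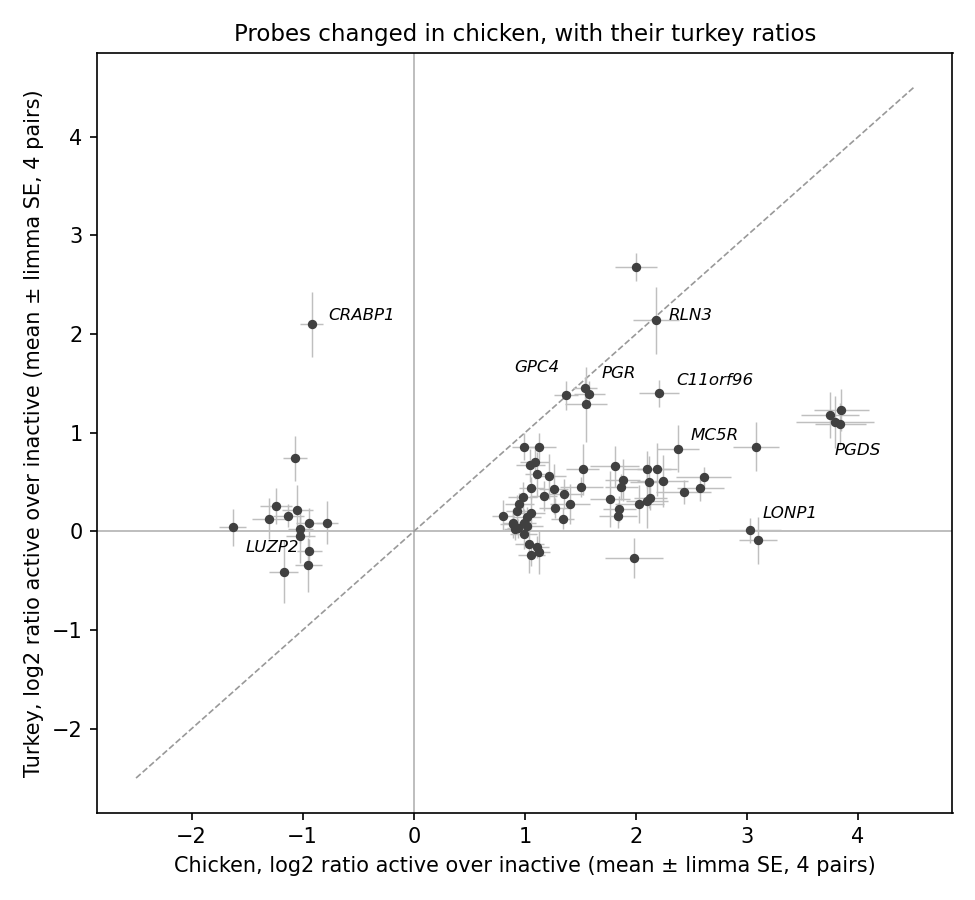
Log2 ratios of active over inactive in chicken (x axis) and turkey (y axis) for the 78 probes called in chicken and tested in turkey, as means with limma SE over 4 pairs; the dashed line marks equal ratios. RLN3 lies on that line, CRABP1 stands at -0.92 in chicken and 2.10 in turkey, and LONP1 at 3.03 and 0.01.

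The difference between species was then tested itself. CRABP1, a retinoic acid binding protein, fell in hens (-0.92 ± 0.13; adjusted p = 0.0252) and stood at 2.10 ± 0.92 in laying turkeys, a difference of 3.02 (adjusted p = 0.0278). The fatty acid binding protein FABP6 was at 0.16 ± 0.04 in chicken and 2.41 ± 0.55 in turkey, a difference of 2.25 (adjusted p = 0.0212). LONP1 rose in hens by 3.03 and stood at 0.01 ± 0.25 in turkey (difference -3.01; adjusted p = 0.0231). Thioredoxin (TXN) was at 1.06 ± 0.21 in chicken and -0.24 ± 0.18 in turkey (difference -1.29; adjusted p = 0.0276). The other named differences were those of LOC769948 at -2.14, CYTH4 at -1.68, LOC416697 at -1.62 and the axonemal dynein gene DNAH17 at -1.21, all from rises in chicken. LOC769948 was above background on only 3 of 8 turkey arrays in the active and 2 of 8 in the inactive channel, so its turkey ratio is mostly one of background, and its second probe missed the threshold for the difference (adjusted p = 0.182). A pair of further DNAH17 probes stood at 0.00 and 0.02 in chicken. CRABP1 was above background on 4 of 8 chicken arrays in the active and 5 of 8 in the inactive channel, and on 8 and 2 of 8 turkey arrays, so both of its ratios involve dim spots.

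In all, 15 of 19695 probes differed between species, 2 with a higher and 13 with a lower ratio in turkey, and 8 carried a symbol. An unadjusted p under 0.05 was reached by 1594, where chance alone gives a share of about 0.05 of the probes tested. The sterol list was lower in turkey than in chicken by a median of -0.18 (adjusted p = 0.00196) and ribosomal proteins higher by 0.11 (adjusted p = 0.00898), but with an estimated correlation these adjusted p-values were 0.113 and 0.86 and neither call held. The estimates themselves were 0.002 and 0.548. The other 18 lists did not pass, and median and mean differed in sign for pituitary transcription factors (0.06 and -0.03), neural lobe (-0.01 and 0.03) and liver and oviduct transcripts (0.04 and -0.10). The count of probes was 1 with the variance prior that follows intensity, and 0 without chicken pair 3, chicken pair 4 or turkey pair 4. With scan day in the model and no pair term it was 22, of which 7 were among the 15. Species also differed in the age of the inactive birds and in the kind of inactivity, and whether the turkey samples were pooled, as those of chicken were, is not stated.

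**Figure D3:**
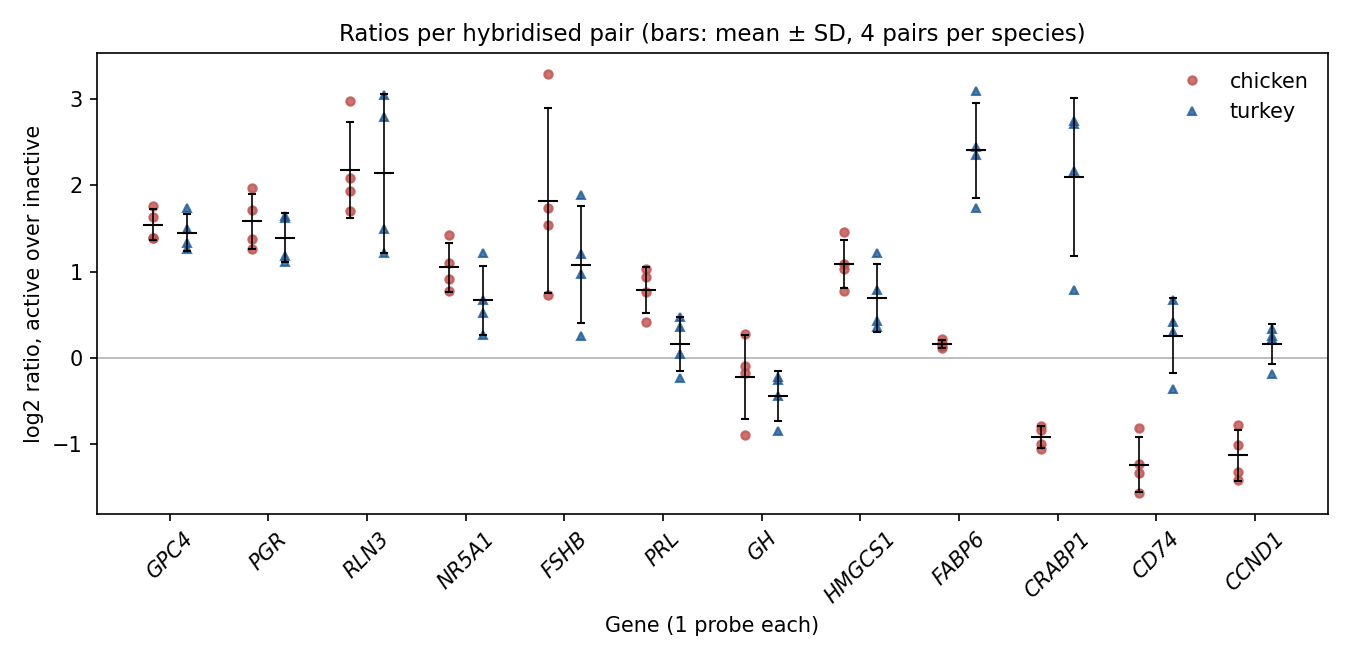
Log2 ratios of active over inactive (y axis) in each of the 4 chicken (circles) and 4 turkey (triangles) pairs for 12 of the named genes, 1 probe each (x axis), with mean and SD. GPC4, PGR and RLN3 lie above 0 in every pair of both species, whereas CRABP1 lies below 0 in every chicken pair and above 0 in every turkey pair.

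Chicken probes gave signal with turkey RNA about as often as with chicken RNA. A mean of 83.9% ± 6.42 (SD, n = 4 pairs) of the probes was above background in turkey and 82.9% ± 7.26 in chicken, a difference of 1.01 points, smaller than the spread between pairs (exact permutation p = 0.8). The first scan day held both species, and its single pairs gave 90.3% in turkey and 84.2% in chicken. The difference was 4.48 with the background of control spots alone and turned to -0.12 with that of empty spots alone, and to -2.53 without chicken pair 3, which had the lowest share at 72.3%. Both arrays of a dye swap correlated below 0 across probes, with a mean r of -0.166 ± 0.168 in chicken and -0.321 ± 0.075 in turkey (exact permutation p = 0.143, n = 4 pairs each). Both pairs of the first scan day gave -0.403 in chicken and -0.426 in turkey. Without chicken pair 1 the difference between species was -0.233 (exact permutation p = 0.0286).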

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

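The tests of detection in turkey, of hybridisation strength, of the granule list, of the shared dye effect and of exchanged channels were chosen after the results were seen. Single pairs stood far from the other 3 of their species in 8 of 147 groups tested, and chance gives about 5%. In chicken these were PGDS in pair 1 (2.32, against 4.17 to 4.49), KIFC2 in pair 2 (-1.34, against -1.0 to -0.95), MGP in pair 1 (-0.10, against -0.75 to -0.64), FLT1 in pair 3 (0.50, against 0.32 to 0.33) and PCSK2 in pair 4 (0.27, against -0.01 to 0.01). In turkey these were PGDS in pair 2 (2.14, against 0.67 to 0.84), LOC769948 in pair 2 (0.82, against 0.30 to 0.33) and CRELD2 in pair 3 (0.19, against 0.59 to 0.64). The ratio of active over inactive differed between species, turkey minus chicken, by 3.02 for CRABP1, -3.01 for LONP1, 2.25 for FABP6, -2.14 for LOC769948, -1.68 for CYTH4, -1.62 for LOC416697, -1.29 for TXN and -1.21 for DNAH17. The median of a list differed by 0.11 for ribosomal proteins and by -0.18 for sterol synthesis.

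Fewer probes passed in turkey, 2 against 79 in chicken. Turkey RNA going undetected by some of these probes stays open, because 98.7% of the probes called in chicken were above background on at least 4 of 8 turkey arrays, but so were 96.8% of all probes. Whether a larger spread between turkey pairs contributed is not settled. The chicken means with the residuals of the turkey pairs gave 101 calls, against 88 with their own, which goes against it. The turkey means gave 22 calls with chicken residuals and 2 with their own, which goes with it. Since 22 stays below 88, spread alone did not account for the whole gap in this exchange. The exchange also treats residuals as unrelated to the size of a probe's ratio. Turning the sign of any 1 turkey pair gave 0 calls, which argues against a pair with its RNAs exchanged. Weaker binding of turkey RNA to chicken probes may still have compressed ratios, since over the probes called in chicken the species difference in inactive-channel level was related to that in ratio at rho = 0.096 (permutation p = 0.404), which decides neither way. A smaller difference between laying and photorefractory turkeys than between hens and pullets, who also differ in age, stays open and untested, as does the pooling of chickens.

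The sterol synthesis list was higher in active birds of both species at the preset correlation, but not with an estimated one (adjusted p = 0.0875 in chicken and 0.261 in turkey), nor in turkey by fry (adjusted p = 0.115). The estimate for this list was -0.001 in chicken and -0.02 in turkey, so correlation among its genes does not account for the lost camera calls. With the channels as coded, a dye bias of its probes is argued against, because its median was above 0 on 16 of 16 arrays and the lowest mean of a species and dye orientation was 0.13. A bias with intensity is argued against by 10000 random lists matched on intensity, of which at most 0.04% had a median as high in either species. A smaller share of cells without hormone granules in active glands is argued against as the whole cause, because granule genes had a median of 0.09 ± 0.07 in chicken (SE over genes), against 0.50 ± 0.10 for the sterol list. The age of the birds in chicken stays open, and no biological explanation was tested.

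Both arrays of a dye swap correlated below 0 across all probes. A dye effect specific to each probe and shared by all arrays is a candidate explanation, since removing the effect estimated from the other 7 pairs raised the correlation in 8 of 8 pairs, to means of 0.074 in chicken and -0.005 in turkey. That effect correlated at 0.812 between species, and its SD over probes, 0.383 in chicken and 0.456 in turkey, exceeded that of the mean ratios, 0.259 and 0.226. With the dye effect removed, single pairs stood at -0.063 to 0.172 in chicken and -0.071 to 0.043 in turkey. Arrays that held the same RNAs thus still agreed little across all probes, which limits what correlations over all probes, also between species, can show. Against channels exchanged on 1 array of each pair, the sterol median lay on the same side of 0 on both arrays in 8 of 8 pairs, and over the probes called in chicken the swap arrays correlated at 0.777 to 0.903 in chicken and -0.011 to 0.388 in turkey. On every array empty spots had a median of 386 to 488 in the first channel and 36 to 53 in the second. This argues against exchanged channel readings. With exchanged samples, both arrays of a pair would give opposite ratios, and the sterol list would lie on opposite sides of 0. The sterol medians therefore argue against that too, although 1 turkey array stood at only 0.027. The probes called in chicken decide less, because they were chosen on the mean of both arrays. No biological explanation was tested.

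Turning the signs of whole pairs gives 8 splits per species, too few for a share under 0.05. In chicken 1 of 8 gave as many as the 79 probes called and the highest other gave 0, and in turkey 1 of 8 gave as many as 2 and the highest other 0. For lists, 2 of 8 splits gave at least the 6 of chicken, and 1 of 8 gave the 4 of turkey, where the highest other gave 2. The other chicken split, with 7 lists, set apart pair 1, the chicken pair scanned on the first day. With scan day as a block and no pair term 6 lists passed, which does not settle whether scan day matters. For the difference between species, 1 of 35 splits of the pairs gave as many as 15 probes and the highest other gave 1. That is the smallest share these splits can give, and the count fell to 0 without chicken pair 3, chicken pair 4 or turkey pair 4. The splits argue against chance for these probes but do not exclude it. As many as 2 lists were given by 15 of 35 splits, and up to 5 by another split, so chance is not excluded for the difference in lists.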

How the results depend on the processing

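Background levels from other spots, the replicate block across species, removal of the dye effect and several settings for lists were chosen after seeing the data. The counts of probes below are for chicken, turkey, their difference and both species, in this order, against 79, 2, 15 and 1. With normexp at offset 0 they were 43 in chicken and 6 for the difference; with scaling between arrays 19, unchanged in turkey, 8 and 0. They were 259, 22, 49 and 5 with both channels above background on every array, where fewer probes are tested; 257, 20, 91 and 8 with all arrays and a random block; and 178, 19 and 7 (chicken, turkey, both) in 1 fit of both species. They were 0, 0, 1 and 0 with the trend and robust prior (1524, 165 and 1523 probes at an unadjusted p under 0.05), 11 in chicken, 1 and 0 without the pairing, and 182, 11, 28 and 7 with control spots alone as background. With scan day as a block and no pair term they were 295 in chicken, 22 in turkey and 8 in both. Without background correction the count was 2 in both, and with a replicate block across species 0 for the difference. The causes were not tested. Leaving out 1 pair gave 0 to 44 in chicken, 0 to 2 in turkey, 0 to 20 for the difference and 0 to 1 in both. The count changed by more than 1.5 times without any of the 4 chicken pairs in chicken, without turkey pairs 1, 3 or 4 in turkey, and without chicken pairs 3 or 4 or turkey pairs 1, 3 or 4 for the difference. In chicken 43 of 43, 19 of 19 and 75 of the 295 were among the 79. The correlation between species, 0.149, was 0.306 with both channels above background and 0.209 with control spots alone, and 0.096 to 0.174 with 1 pair left out. The difference in detection, 1.01 points, was -0.12 with empty spots alone, 4.48 with control spots alone, -1.89 with BlueFuse's probability, and -2.53, -1.12 and -0.22 without chicken pair 3, turkey pair 1 and turkey pair 3 (-2.53 to 3.70 over pairs left out). The difference in dye swap r was -0.233 to -0.102 with 1 pair left out, past the threshold only without chicken pair 1. Lists past the threshold, 6, 4 and 2, were 0, 0 and 0 with an estimated correlation and 1, 0 and 0 with fry; leaving out 1 pair gave 4 to 7, 3 to 4 and 1 to 4. Of 1408 values of named probes under other settings, 1180 kept direction and side, 152 lost the call, 71 gained it and 5 reversed; with 1 pair left out 133 of 375 lost it and 6 reversed. Reversals in chicken were POMC (0.02 with print-tip loess, 0.01 with the deposited table, 0.04 without pair 1 or 3; -0.15 to 0.04), CGA (-0.05 with scaling; -0.03, -0.01 and -0.04 without pair 1, 3 or 4; -0.04 to 0.13), GH (0.00 without pair 2; -0.39 to 0.00) and the ribosomal list (0.078 without pair 1; -0.082 to 0.078 over pairs left out). In turkey STARD4 was at 0.50, and at -0.21 with print-tip loess and -0.08 with the deposited table. The median of all probes stayed within 0.02 of 0 under every scaling, but normalization within arrays largely sets it there, so it is no check of the ratios. Detection at 3 SDs or at 1.5 times background was not run, since the files hold no local background. In the first channel empty spots read up to the level of dim probes (median 428.2), which limits ratios of weak transcripts.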

Other observations

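GREB1 stood at 1.56 ± 0.62 in hens (adjusted p = 0.0686) and at 1.05 in laying turkeys (adjusted p = 0.648). PGR, whose spots are dim, stood at 1.58 ± 0.32 in hens and, without passing over all probes, at 1.39 ± 0.28 in laying turkeys (adjusted p = 0.113). The species did not differ for PGR (difference -0.19; adjusted p = 0.862), which does not show that they respond alike. Albumin (ALB) stood at 0.75 ± 0.17 in laying turkeys and passed when adjusted over its list alone. In chicken, the vascular genes of the endothelium list went both ways when adjusted over the list alone, as FLT1 rose (0.36 ± 0.09) and ERG (-0.67 ± 0.48) and PECAM1 (-0.57 ± 0.26) fell. The growth factor gene CCN2 of the immediate early list fell on the same terms (-0.91 ± 0.51), and the calcium binding protein SCGN of the granule list rose (0.73 ± 0.34).

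A group of probes without a symbol rose in hens as strongly as PGDS. RIGG07497 stood at 3.85 ± 0.25 and RIGG07486 at 3.84 ± 0.23 (SE, n = 4 pairs; adjusted p = 0.011 for both), and they were chosen after their values were seen. In turkey RIGG07497 was at 1.23 and RIGG07486 at 1.09, against 1.11 for PGDS. RIGG07510 stood at 3.75 in chicken and 1.18 in turkey, and RIGG07485 was somewhat lower at 3.08 and 0.86. The library numbers of these probes lie close to that of the PGDS probe, RIGG07498. Whether they share a transcript or a signal with it is unknown, so their rises and that of PGDS may not be separate changes, although each probe is counted. The files give no name for these unnamed probes, so it is unknown which transcripts they measure.

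The array also held 18 custom oligonucleotides, of which none passed in either species by limma. Probes A11 and A12, chosen after their values were seen, belong to 1 set of 5 that carry a percentage in their label, 100 for A11 and 80 for A12. In turkey A11 stood at 1.02 ± 0.36 (SD, n = 4 pairs; 4 of 4 pairs; adjusted p = 0.405) and A12 at 0.71 ± 0.22 (4 of 4 pairs; adjusted p = 0.487), and in chicken at -0.27 ± 0.13 and -0.15 ± 0.28. The difference between species for A11 was 1.29 (adjusted p = 0.0527). The members of the set labelled 70, 60 and 50 stood at 0.11, 0.07 and -0.06 in turkey. In the other 2 sets of 5 with such labels, those labelled 100 stood at 0.06 (A06) and 0.18 (A01) and those labelled 80 at 0.24 (A07) and 0.03 (A02). The files do not say what the percentage refers to. Each label also carries the identifier of a sequence record, shared by the members of a set. These records were not looked up, so the target transcripts are not named here.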
